A study of Homo sapiens and Mus musculus and Bos taurus with 52 samples.

How the data were processed

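Per the labels, human embryos left over from treatment were cultured, and the embryos of each stage were put into 3 groups that were pooled, each group being 1 replicate. Mouse embryos were flushed from the oviducts, and bovine oocytes were matured and fertilised in culture. Total RNA went through 3 rounds of amplification, was labelled with biotin and was hybridised to Affymetrix arrays. The descriptions of the human and mouse 2-cell, 4-cell and 8-cell samples speak of an undivided zygote, against their titles and characteristics, from which the stage was taken, and every stage value rests on that choice. The labels call the arrays of a stage biological replicates without naming the parents of the embryos in each pool. The p-values therefore measure only the spread between samples, which may be technical.

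The authors deposited 1 intensity per probe set and array on a linear scale. How probes were summarised into these intensities, and whether and how arrays were scaled to each other, is not given in the sources used here. Values ran from 0.57 to 12985.1 in human, from 0.49 to 15337.2 in mouse and from 0.47 to 21288.1 in bovine, and no 2 arrays were identical.

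Human tables held 54613 probe sets besides 62 controls, of which 41091 carried 1 gene symbol in the array annotation, 1801 several and 11721 none. Mouse tables held 22626 besides 64 controls, with 20380, 691 and 1555, and the bovine ones 24016 besides 112 controls, with 13292, 86 and 10638. Where several probe sets carried the same symbol, the one with the highest mean over all arrays of the species stood for the gene. This left 19775 human, 12393 mouse and 9155 bovine genes, of which 10523, 4956 and 2913 had several probe sets. No gene was filtered out. The main scale was log2(intensity + 16) without further scaling. Genes were matched between species by symbol without regard to case.

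Each species was fitted once over all its stages with limma (lmFit and eBayes), with no batch or replicate term, and stages were compared with limma's moderated 2-sided test. The residual degrees of freedom were 12 in human and mouse and 8 in bovine, with prior degrees of freedom of 4.19, 4.26 and 2.19. P-values were adjusted by Benjamini and Hochberg over the genes of a comparison, and genes with adjusted p under 0.05 were called. The comparisons were every pair of successive stages, the 1-cell stage against the blastocyst, and any difference between stages (limma's moderated F). The tools were R 4.3.3 with limma 3.58.1, and Python 3.11.15 with matplotlib 3.10.9 for the plots.

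The gene lists and the alternative settings were fixed before the data were examined. The 16 lists were written from general knowledge of early development: oocyte and maternal-effect genes, early genome activation, ribosomal proteins, ribosome biogenesis with RNA polymerase I, proteasome subunits, nuclear genes of oxidative phosphorylation, glycolysis and glucose transport, cholesterol synthesis, pluripotency and epiblast, trophectoderm and epithelium, primitive endoderm, DNA methylation and chromatin enzymes, mitosis, stress response, cumulus and granulosa cell markers, and markers of oviduct, blood and sperm cells. Lists were tested with limma's camera, 2-sided, with a preset correlation between genes of 0.01 and again with a correlation estimated from the data, adjusted over the lists of a comparison. Lists with fewer than 5 measured genes were only described. Members were also tested with p-values adjusted over the list alone.

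Genes were named by rule. In each species the main comparisons were the 1-cell stage against the blastocyst and the successive pair of stages with the highest percent called. There the 8 rising and 8 falling genes with the largest absolute log2 change were named among those with adjusted p under 0.05, all arrays of one stage above all of the other, and a mean in the higher stage above the median of all genes. In every other pair of successive stages 2 per direction were named. Placeholder symbols were passed over, as were XIST and Y-linked genes, which are not reported. List members could be named in addition, as could, for each pair of species, the 5 genes with the largest opposite changes.

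Alternative settings were quantile normalization, subtraction of each array's median, leaving out the 30% of genes with the lowest mean, pseudocounts of 1 and 64, the replicate number as a block, the mean of all probe sets of a gene, all probe sets in place of genes, eBayes with trend and robust variance, only the arrays of the compared stages, and each array left out in turn. A count was taken as moved when it differed from the main value by more than 1.5-fold, and a correlation when it differed by more than its SE from leaving out single arrays. Leaving out the 4 doubted arrays was added after the data were seen.

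The procedure was tested on simulated data with 200 changed genes per species. Of genes changed 2-fold, 4-fold and 16-fold at the step with most calls it recovered 52%, 100% and 100% in human. Mouse had 45%, 94% and 100%, and bovine 0%, 26% and 76%. Unchanged genes made up 8.43%, 2.74% and 7.27% of the calls, and 0 genes were called in steps without a change. Bovine counts are not comparable in size with the others. Real steps had 7350, 4038 and 1513 calls, so these rates do not carry over.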

Results

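Messenger RNA was measured in preimplantation embryos of human, mouse and cattle on 1-channel Affymetrix arrays, with a separate array type for each species. The human and the mouse series held 18 arrays each, 3 at each of 6 stages, which were the 1-cell, 2-cell, 4-cell and 8-cell embryo, the morula and the blastocyst. The bovine series held 16 arrays, 2 at each of 8 stages, among them the oocyte and the 16-cell embryo. Levels below are log2(intensity + 16) of 1 probe set per gene, as the mean ± SD over the arrays of a stage, with n = 3 in human and mouse and n = 2 in bovine. Over all genes the median level was 5.80 in human, 5.93 in mouse and 7.52 in bovine.

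Changes are log2 differences between stage means with the standard error (SE) from limma, and a gene rose or fell where limma's adjusted p was under 0.05. The adjusted p of a gene list is from limma's camera with a correlation estimated from the data, unless a preset one is named. The comparisons asked which transcripts the oocyte left to the embryo, when the embryo's own transcription replaced them, and whether human, mouse and bovine embryos did so with the same genes. 4 arrays were doubted after the data were seen. Human 4-cell replicate 2, human 8-cell replicate 3 and bovine 16-cell replicate 1 had high cumulus cell markers. The kept human 8-cell replicate 1 and bovine 8-cell replicate 2 had some too. Mouse blastocyst replicate 3 had a mean r of 0.742 with its own stage. By this r human 4-cell replicate 2 had 0.967 against 0.970 and 0.975. Human 2-cell replicate 3 was kept with 0.957 against 0.972 and 0.971. Counts of all genes without the doubted arrays are given beside the main ones. List counts are given where rises or falls then differed by 2 or more.

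**Figure D1:**
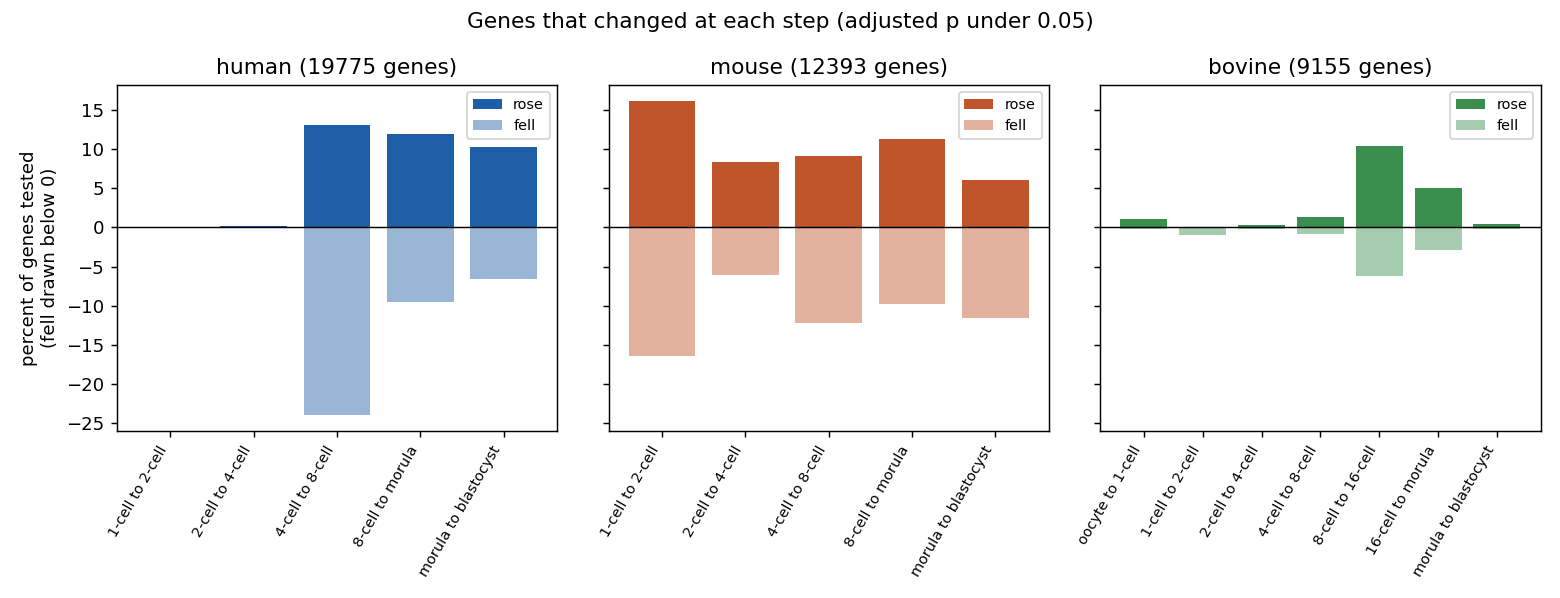
Percent of genes that rose (above 0) and fell (below 0) in each step between successive stages, by species, at limma's adjusted p under 0.05. The highest percents were at the 4-cell to 8-cell step in human (37.2%), the 1-cell to 2-cell step in mouse (32.6%) and the 8-cell to 16-cell step in bovine (16.5%), but in bovine not with only the arrays of the compared stages (2.56%, against 3.54% for 16-cell to morula).

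In the human embryo, the 1-cell and the 2-cell stage both carried abundant oocyte transcripts. BTG4, which drives the decay of maternal mRNA, stood at 12.36 ± 0.13 and 11.69 ± 0.50. The DNA methyltransferase DNMT1 stood at 12.63 ± 0.02 and 12.52 ± 0.03, and its partner UHRF1 at 12.24 ± 0.06 and 12.26 ± 0.15. ZSCAN4, a marker of early genome activation, was at 4.81 ± 0.15 and 5.90 ± 0.83. Of 19775 genes, 0 passed limma's adjusted p, although 1608 had an unadjusted p under 0.05. Without the doubted arrays 1 gene fell, and the same number was called without 1-cell replicate 2. In none of the 16 lists was a gene called over all genes. When adjusted over the list alone 2 early activation genes rose, and 3 mitosis genes and 1 ribosome biogenesis gene fell. 5 lists passed with the preset correlation, mitosis with the lowest adjusted p = 0.000360, and none with an estimated correlation, where mitosis and early activation had adjusted p = 0.571.

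From the 2-cell to the 4-cell stage a few human genes of early genome activation rose. These were PRAMEF12 by 2.74 (SE 0.45), RFPL2 by 2.37 (SE 0.36) and KHDC1L by 2.29 (SE 0.37), or 3 of the 15 measured members, and 8 when adjusted over the list alone. The list as a whole had adjusted p = 0.0876. FAM90A1, of a primate gene family, rose by 3.32 (SE 0.47) from 6.99 ± 0.84 to 10.31 ± 0.56, and the pseudogene FRG2EP by 3.24 (SE 0.47). The nucleolar protein FBL rose by 1.63 (SE 0.26), the proteasome subunit PSMD8 by 1.78 (SE 0.30), the glucose transporter SLC2A3 by 1.25 (SE 0.20) and the ribosomal protein RPL29 by 1.08 (SE 0.17). The non-coding LINC01896 changed by -1.24 (SE 0.24) and STRIP2, a cytoskeletal scaffold, by -1.03 (SE 0.20). In all 32 genes rose and 5 fell, which is 0.187% of genes. Without the doubted arrays 2 rose and 0 fell, and none of the early activation list or of the genes named here was called. The percent was 0 without 2-cell replicate 2, 2-cell replicate 3, 4-cell replicate 2 or 4-cell replicate 3 and with only the arrays of the compared stages, and 0.516 without 4-cell replicate 1. Cumulus markers had a median change of 0.23 with no gene called (adjusted p = 0.314, and 0.00158 with the preset correlation). No cholesterol synthesis gene was called, though 8 passed when adjusted over the list alone, and the list had adjusted p = 0.217.

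The step from the 4-cell to the 8-cell stage was the largest in human. Genes known to mark human genome activation rose. KLF17, a transcription factor, rose by 4.59 (SE 0.38) from 5.36 ± 0.59 to 9.95 ± 0.25, and KHDC1L by 4.59 (SE 0.37) from 7.75 ± 0.24 to 12.34 ± 0.08. The germline cyclin CCNA1 rose by 3.85 (SE 0.51), the phosphate transporter SLC34A2 by 3.99 (SE 0.30), TMEM92 by 3.68 (SE 0.22) and ZSCAN4 by 2.68 (SE 0.53) to 11.17 ± 0.08. At the same step the oocyte's transcripts fell. BTG4 fell from 11.47 ± 0.21 to 7.53 ± 0.40, a change of -3.94 (SE 0.23). The receptor KIT changed by -3.71 (SE 0.44), the germ cell RNA binder DAZL by -3.46 (SE 0.31), the translational regulator CPEB1 by -2.94 (SE 0.25), the meiotic kinase MOS by -2.85 (SE 0.25) and the growth factor BMP15 by -2.66 (SE 0.18).

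Of the oocyte and maternal-effect genes 0 rose and 26 of 33 fell (27 when adjusted over the list alone, 23 without the doubted arrays), with adjusted p = 0.039 and 0.124, no longer passing, without the doubted arrays. Of the 15 early activation genes 9 rose and 1, the translation factor EIF1AX, changed by -0.62 (SE 0.22). When adjusted over the list alone 10 rose and 1 fell, and without the doubted arrays 10 rose and 0 fell. Their list had adjusted p = 0.0935. Signs of RNA amount and quality moved with this step. Genes above a level of 8 numbered 2195, 2295 and 3486 in the 8-cell arrays, against 3883 to 4077 in the 4-cell ones. The 3 prime minus 5 prime difference of the GAPDH control was 4.16, 3.08 and 3.40, against 2.87 to 3.18, and that of the actin control 5.00, 4.16 and 4.55, against 3.25 to 4.19. These values moved together with the falls of the oocyte list and of the mitosis and chromatin lists below. Of 19775 genes 2602 rose and 4748 fell, or 37.2%. Without the doubted arrays 2195 rose and 4871 fell, or 35.7%. Quantile normalization gave 3665 that rose and 3927 that fell, so that the excess of falls depended on the scaling of the arrays. Changes over 2-fold numbered 1267 up and 3658 down.

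The largest rises at the human 4-cell to 8-cell step were in genes of varied function. FAM151A rose by 6.96, SE 0.21, adjusted p = 3.64e-12, from 4.68 ± 0.30 to 11.64 ± 0.05. The secreted synaptic protein CBLN1 rose by 6.41 (SE 0.32), SLC2A3 by 5.71 (SE 0.20), the H3K4 demethylase KDM5B by 5.54 (SE 0.26), the signalling adaptor GRB2 by 5.33 (SE 0.32), the germ cell alkaline phosphatase ALPG by 5.32 (SE 0.20), the actin-associated KPTN by 5.18 (SE 0.34) and the RNA-binding NONO by 5.16 (SE 0.16). The largest falls were in RIPOR3, -4.49, SE 0.22, adjusted p = 8.39e-10, and in the MYC antagonist MXD1, -4.39 (SE 0.39). The glycogen-targeting phosphatase subunit PPP1R3D changed by -4.39 (SE 0.23), the amino sugar enzyme GNPDA2 by -4.35 (SE 0.25) and the deubiquitinase MINDY3 by -4.34 (SE 0.33). 3 zinc finger genes fell as well, ZSWIM3 by -4.22 (SE 0.24), ZBTB49 by -4.21 (SE 0.33) and ZNF571 by -4.20 (SE 0.30).

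Regulators of cell identity and of chromatin split in both directions at this human step. NANOG rose by 4.02 (SE 0.37), ZFP42 by 3.07 (SE 0.19), DPPA2 by 2.81 (SE 0.20) and SOX2 by 2.31 (SE 0.54) (1.02, SE 0.37, without the doubted arrays), while KLF2 changed by -3.08 (SE 0.20). Of the 28 pluripotency genes 10 rose and 5 fell (adjusted p = 0.507). The trophectoderm factor TFAP2C rose by 5.15 (SE 0.26), whereas the junction genes TJP1, EPCAM and CDH1 changed by -2.52 (SE 0.26), -2.08 (SE 0.51) and -1.997 (SE 0.37). Of the 41 trophectoderm genes 8 rose and 4 fell (adjusted p = 0.606). GATA6 of the primitive endoderm rose by 3.24 (SE 0.32), with 4 of 25 genes of its list up and 4 down. Among 44 DNA methylation and chromatin enzymes 8 rose, such as KDM5B, and 22 fell, such as DNMT3B by -3.69 (SE 0.49) and TET3 by -3.62 (SE 0.34) (7 and 20 without the doubted arrays). Of 37 mitosis genes 2 rose and 22 fell, BUB1B by -3.64 (SE 0.25) and ANLN by -3.39 (SE 0.22) the most, and without the doubted arrays 2 rose and 23 fell (adjusted p = 0.507).

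Genes of the protein and energy supply of the human embryo also changed at the 4-cell to 8-cell step. The ribosome assembly genes IMP4, NOP58 and FBL rose by 3.47 (SE 0.17), 3.15 (SE 0.20) and 2.74 (SE 0.26), and NOC3L and POLR1B changed by -2.02 (SE 0.26) and -1.87 (SE 0.18). In that list 20 of 51 rose and 10 fell (18 and 10 without the doubted arrays; adjusted p = 0.507). Of 52 ribosomal protein genes 12 rose and 1 fell (9 and 1 without the doubted arrays; adjusted p = 0.606), and of 30 proteasome genes 4 rose and 11 fell (2 and 13; adjusted p = 0.816). Of 68 oxidative phosphorylation genes 15 rose and 7 fell, but 15 and 12 without the doubted arrays (adjusted p = 0.713). In glycolysis 7 of 22 rose and 3 fell, with SLC2A3 and the enolase ENO2 at the top, 3.72 (SE 0.31), and the kinase PDK1 at the bottom, -2.76 (SE 0.42) (9 and 4 without the doubted arrays). Of 19 cholesterol synthesis genes 4 rose and 5 fell, but 2 and 7 without the doubted arrays. Of 24 stress genes 8 rose and 4 fell, of 26 cumulus and granulosa cell markers 2 rose and 0 fell, and of 19 oviduct, blood and sperm markers 2 rose and 2 fell.

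Between the human 8-cell stage and the morula further oocyte transcripts fell and more genes of the trophectoderm and epithelium list rose than fell. BCL2L10, a cell death regulator of the oocyte, changed by -4.64 (SE 0.27), OOSP2 by -4.01 (SE 0.35), the oocyte linker histone H1-8 by -3.63 (SE 0.15) and NLRP4 by -3.58 (SE 0.33). Of 33 oocyte genes 1 rose and 24 fell (2 and 26 when adjusted over the list alone, 1 and 24 without the doubted arrays), with adjusted p = 0.00278. UHRF1 changed by -4.36 (SE 0.26) and DNMT1 by -3.03 (SE 0.27), while the methylation cofactor DNMT3L rose by 3.65 (SE 0.43). The prostaglandin synthase PTGES rose by 4.35 (SE 0.53), the water channel AQP3 by 3.83 (SE 0.26) and the keratin KRT18 by 3.43 (SE 0.52). In the trophectoderm list 16 of 41 rose and 4 fell (13 and 3 without the doubted arrays; adjusted p = 0.338).

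Genes of early activation that had peaked at the human 8-cell stage fell again at the 8-cell to morula step. RFPL2 changed by -5.04 (SE 0.36) and MBD3L2 by -3.50 (SE 0.85), whereas TMEM92 rose by 1.02 (SE 0.22), so that 1 of 15 rose and 8 fell (adjusted p = 0.338). L1TD1 and TBX3 of the pluripotency list rose by 3.19 (SE 0.42) and 3.09 (SE 0.31), and OTX2 changed by -2.81 (SE 0.32), with 12 of 28 up and 4 down (adjusted p = 0.338). Ribosome biogenesis had 18 of 51 up and 0 down (25 up both when adjusted over the list alone and without the doubted arrays; adjusted p = 0.327). Oxidative phosphorylation had 13 of 68 up and 3 down (30 and 1 without the doubted arrays), mitosis 17 of 37 up and 4 down (19 and 4), and chromatin enzymes 12 of 44 up and 5 down (16 and 5). The largest rises of all genes were in the asparaginase ASRGL1, 4.63 (SE 0.31), and the receptor FGFR3, 4.63 (SE 0.50). The largest falls were in IGFBP7, -5.92 (SE 0.79), and the protease HTRA1, -5.43 (SE 0.74), secreted proteins whose 8-cell levels of 10.83 ± 1.46 and 10.47 ± 1.42 varied widely between arrays. In all 2355 genes rose and 1872 fell, or 21.4% (3175 and 1767, or 25.0%, without the doubted arrays), and 10.8% were called with only the arrays of the compared stages.

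Markers of cumulus and granulosa cells, the somatic cells around the oocyte, moved together with those falls. From the human 8-cell stage to the morula the steroid carrier STAR changed by -3.90 (SE 0.84), the activin antagonist FST by -3.77 (SE 0.57), the steroid enzyme HSD3B2 by -3.40 (SE 1.00; without the doubted arrays -2.15, SE 0.76, adjusted p = 0.0512), GREM1 by -3.19 (SE 0.66) and VIM by -2.90 (SE 0.54). Of the 26 markers 0 rose and 10 fell (14 when adjusted over the list alone, 7 without the doubted arrays; adjusted p = 0.338). In the human 8-cell arrays STAR stood at 9.13, 6.77 and 10.49 and HSD3B2 at 8.76, 5.28 and 10.77, and in the 4-cell arrays STAR stood at 7.65, 10.82 and 8.32. The cholesterol synthesis genes HMGCS1, FDPS and MSMO1 had the same order as STAR within each of these stages, HMGCS1 at 10.07, 7.99 and 10.77 in the 8-cell arrays. Of 19 cholesterol genes 0 rose and 6 fell (4 without the doubted arrays), HMGCS1 by -2.26 (SE 0.71; without them -1.68, SE 0.65, adjusted p = 0.0753) and DHCR7 by -2.23 (SE 0.42). The primitive endoderm list had 2 of 25 up and 6 down, with FN1 at -4.20 (SE 0.41) and LAMA1 at 2.97 (SE 0.50), and of 24 stress genes 3 rose and 7 fell, CDKN1A by -3.42 (SE 0.65) (5 and 7 without the doubted arrays).

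**Figure D2:**
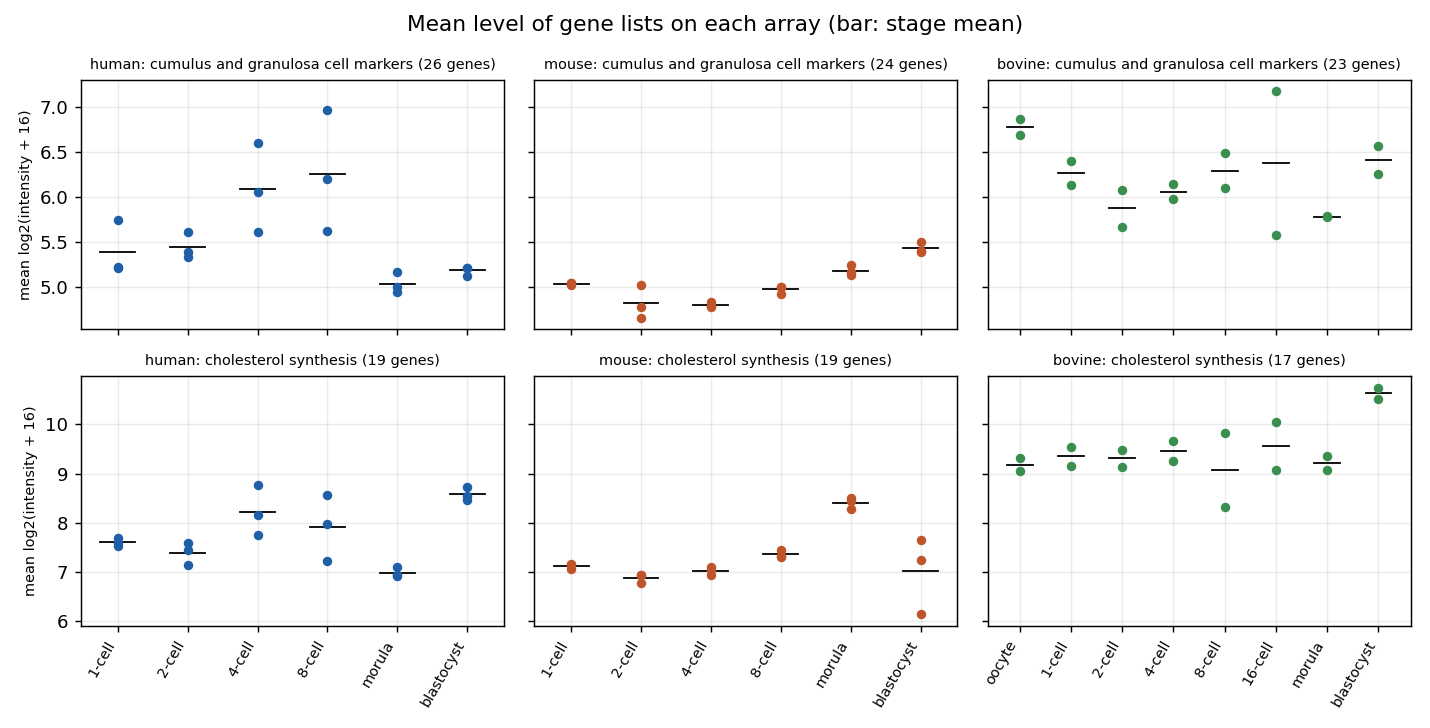
Mean log2(intensity + 16) of the cumulus and granulosa cell markers and of the cholesterol synthesis genes in each array, by stage and species, with a bar at the stage mean. The human 8-cell and 4-cell arrays and bovine 16-cell replicate 1 spread apart within their stage.

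From the human morula to the blastocyst trophectoderm genes rose. KRT19 rose by 4.39 (SE 0.46) from 5.81 ± 1.52 to 10.20 ± 0.13, the fatty acid binder FABP3 by 4.55 (SE 0.52), the epithelial GTPase RAB25 by 4.34 (SE 0.42), the claudin CLDN4 by 3.92 (SE 0.27) and the transcription factor GATA3 by 2.53 (SE 0.30). Of 41 genes 25 rose and 0 fell (27 up both when adjusted over the list alone and without the doubted arrays), with adjusted p = 0.0295. Primitive endoderm genes rose with them, the receptor LRP2 by 5.48 (SE 0.31), LAMC1 by 3.46 (SE 0.28) and BMP2 by 2.43 (SE 0.28), 9 of 25 in all (10 both over the list alone and without the doubted arrays; adjusted p = 0.0621). Cholesterol synthesis rose, SQLE by 3.55 (SE 0.41), HMGCS1 by 3.38 (SE 0.71) and DHCR7 by 3.31 (SE 0.42), with 12 of 19 up and 0 down (15 over the list alone, 14 without the doubted arrays; adjusted p = 0.132).

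Other human genes fell between the morula and the blastocyst. Of 33 oocyte genes 2 rose and 15 fell, ZP2 of the egg coat by -3.66 (SE 0.21) and NLRP4 by -3.53 (SE 0.33), with 2 and 17 over the list alone, 2 and 16 without the doubted arrays, and adjusted p = 0.0295, or 0.0547 without the doubted arrays, where it no longer passed. Of the early activation genes 0 rose and 6 of 15 fell, TMEM92 by -3.95 (SE 0.22), ZSCAN4 by -3.86 (SE 0.53) and KLF17 by -3.68 (SE 0.38) (adjusted p = 0.0621). SOX2 changed by -2.59 (SE 0.54) and NANOG by -1.27 (SE 0.37), while IFITM1 rose by 3.70 (SE 0.43), with 5 of 28 pluripotency genes up and 7 down. Oxidative phosphorylation had 14 of 68 up and 0 down (26 up without the doubted arrays; adjusted p = 0.632). The steroid enzyme HSD17B1 rose by 5.22 (SE 0.81), and the cell death gene BIK and CBLN1 changed by -4.67 (SE 0.36) and -4.52 (SE 0.32). In all 2046 genes rose and 1289 fell, or 16.9% (2392 and 1458, or 19.5%, without the doubted arrays), and 1893 rose and 1952 fell under quantile normalization.

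Over the whole human course, from the 1-cell stage to the blastocyst, the oocyte programme gave way to an epithelial one. BCL2L10 fell from 12.52 ± 0.05 to 4.91 ± 0.18, a change of -7.60, SE 0.27, adjusted p = 1.3e-12, and NLRP4 changed by -7.60 (SE 0.33). The receptor GPR39 changed by -7.56 (SE 0.18), NLRP11 by -7.54 (SE 0.37), the AKT cofactor TCL1A by -7.43 (SE 0.35), OOSP2 by -7.38 (SE 0.35), FAM13A by -7.37 (SE 0.22) and LINC02204 by -7.36 (SE 0.18). FAM151A rose by 7.27 (SE 0.21), KRT18 by 6.99 (SE 0.52) to 12.72 ± 0.06, KHDC1L by 6.85 (SE 0.37), SLC2A3 by 6.78 (SE 0.20), FGFR3 by 6.75 (SE 0.50), ALPG by 6.64 (SE 0.20), the laminin LAMA1 by 6.59 (SE 0.50) and the calcium binder S100A14 by 6.49 (SE 0.75). Of 33 oocyte genes 0 rose and 30 fell, also without the doubted arrays (adjusted p = 0.00262), and over the list alone 1 rose and 30 fell. Of 41 trophectoderm genes 31 rose and 2 fell, also without the doubted arrays (adjusted p = 0.0366), and over the list alone 32 rose and 2 fell. Of 19775 genes 4389 rose and 4898 fell, or 47.0% (4575 and 5022, or 48.5%, without the doubted arrays), 4691 and 4483 under quantile normalization, and 60.1% differed between any stages, with and without the doubted arrays.

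Metabolic and other groups shifted over the human course as well, though none of their lists passed with an estimated correlation. Oxidative phosphorylation had 49 of 68 genes up and 1 down (adjusted p = 0.372), ribosomal proteins 21 of 52 up and 1 down (adjusted p = 0.437) and ribosome biogenesis 27 of 51 up and 5 down (adjusted p = 0.299). In glycolysis 15 of 22 rose, LDHB by 5.27 (SE 0.60) next to SLC2A3, and 1 fell, PDK1 by -5.44 (SE 0.42). Proteasome subunits had 14 of 30 up and 6 down, cholesterol synthesis 10 of 19 up and 3 down (13 and 3 without the doubted arrays), and stress genes 12 of 24 up and 6 down. ZFP42 and KLF4 of the pluripotency list rose by 6.03 (SE 0.19) and 5.41 (SE 0.40) and OTX2 changed by -6.85 (SE 0.32), with 16 of 28 up and 4 down. Of 25 primitive endoderm genes 11 rose and 3 fell, of 15 early activation genes 6 rose and 1 fell, and of 37 mitosis genes 6 rose and 21 fell. Chromatin enzymes were divided, with 16 of 44 up, DNMT3L by 5.97 (SE 0.43) and TDG by 5.15 (SE 0.50), and 18 down, KDM1B by -5.39 (SE 0.35), a median of -0.23 and a mean of 0.11. Cumulus markers had 3 of 26 up and 3 down (3 and 7 without the doubted arrays), and oviduct, blood and sperm markers 3 of 19 up and 2 down.

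In the mouse the embryo's own programme appeared already between the 1-cell and the 2-cell stage. The PRAME family genes Pramel7 and Pramel6, known from early mouse embryos, rose by 6.82 (SE 0.21) and 6.61 (SE 0.30), Pramel7 from 4.48 ± 0.13 to 11.30 ± 0.21. The ribosomal protein genes Rpsa, Rps9 and Rpl10a rose by 5.03 (SE 0.21), 4.66 (SE 0.23) and 4.63 (SE 0.21). Dppa4 of the pluripotency list rose by 6.10 (SE 0.22) and Kdm5b by 6.42 (SE 0.48). At the same time the oocyte growth factor Gdf9 fell from 12.71 ± 0.36 to 8.84 ± 0.27, a change of -3.88 (SE 0.21), and Mos and Dazl changed by -3.28 (SE 0.23) and -3.26 (SE 0.23).

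Of 41 mouse ribosomal protein genes 37 rose and 0 fell at the 1-cell to 2-cell step (37 and 1 both over the list alone and without the doubted array), with adjusted p = 0.00683. Of 19 oocyte genes 0 rose and 14 fell (16 both over the list alone and without the doubted array; adjusted p = 0.00683). Early activation had 9 of 17 up and 2 down, with and without the doubted array and over the list alone (adjusted p = 0.0173, and 0.0609, no longer passing, without the doubted array), the falls being Mbd3l2 by -2.11 (SE 0.18) and Klf17 by -0.99 (SE 0.28). Ribosome biogenesis had 39 of 55 up and 2 down, Taf1d by 4.05 (SE 0.38) and Gnl3 by 3.75 (SE 0.22) among the rises (40 and 4 over the list alone, 42 and 4 without the doubted array; adjusted p = 0.123, and 0.0486 without the doubted array). Of 12393 genes 2008 rose and 2030 fell, or 32.6%. Without the doubted array 2591 rose and 2737 fell, or 43.0%. Changes over 2-fold numbered 1553 up and 1452 down.

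The largest mouse rises at this step were in Selenos, a selenoprotein of the endoplasmic reticulum, 7.47 (SE 0.44), and in the nucleotide kinase Nme2, 7.35, SE 0.16, adjusted p = 1.15e-14, from 5.09 ± 0.21 to 12.43 ± 0.21. The homeobox gene Crxos rose by 6.98 (SE 0.20), the survival factor Mcl1 by 6.69 (SE 0.21) (2.37, SE 0.18, without the doubted array, where another probe set stood for it), the phosphatase Nudt4 by 6.63 (SE 0.29) and the mitochondrial import receptor Tomm20 by 6.63 (SE 0.25). The largest falls were in the DNA repair gene Dclre1a, -5.48 (SE 0.35), and the oocyte linker histone H1f8, -5.05, SE 0.20, adjusted p = 1.11e-11. The fatty acid elongase Elovl5 changed by -4.83 (SE 0.52), the glutaredoxin Glrx by -4.80 (SE 0.27), the hypoxia factor Hif1a by -4.72 (SE 0.46), the chaperone Dnajb4 by -4.64 (SE 0.48), the signalling regulator Rgs2 by -4.56 (SE 0.51) and Ndfip1 by -4.54 (SE 0.49).

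Other mouse groups were divided at the 1-cell to 2-cell step. Of 33 chromatin enzymes 7 rose, Hdac1 by 4.06 (SE 0.25) after Kdm5b, and 15 fell, Eed by -2.95 (SE 0.26), Uhrf1 by -2.85 (SE 0.28) and Dnmt1 by -2.81 (SE 0.34). Of 26 pluripotency genes 11 rose and 3 fell, Pou5f1 by -1.28 (SE 0.25) (12 and 5 without the doubted array). Of 35 mitosis genes 10 rose, Cdc25c by 3.18 (SE 0.22), and 16 fell, Bub1b by -3.93 (SE 0.21) (13 and 19 without it). Proteasome genes had 16 of 34 up and 9 down (18 and 10 without it), oxidative phosphorylation 30 of 70 up and 11 down (34 and 15), with adjusted p = 0.711 with an estimated correlation for both, and glycolysis 2 of 18 up and 6 down (5 and 7). Stress genes had 8 of 24 up, Trib3 by 5.37 (SE 0.44), and 3 down (9 and 5). Cholesterol synthesis had 6 of 19 up and 6 down (8 and 7), trophectoderm 4 of 39 up and 7 down (7 and 10), primitive endoderm 2 of 25 up and 1 down (3 and 5), cumulus markers 0 of 24 up and 4 down, and oviduct, blood and sperm markers 0 of 18 up and 3 down.

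From the mouse 2-cell to the 4-cell stage genes of protein and energy supply rose. Of 41 ribosomal protein genes 29 rose and 0 fell (34 over the list alone, 33 without the doubted array; adjusted p = 0.0177). Proteasome subunits had 21 of 34 up and 0 down (24 and 25; adjusted p = 0.0711), and oxidative phosphorylation 30 of 70 up and 1 down (36 and 1 over the list alone, 43 and 1 without the doubted array; adjusted p = 0.131, and 0.0403 without the doubted array). Of 19 oocyte genes 0 rose and 10 fell (11 both over the list alone and without the doubted array), Bcl2l10 by -3.06 (SE 0.20), with adjusted p = 0.00637. The growth factor receptor partner Tdgf1 rose by 4.06 (SE 0.62) and the transcription factor Foxa1 by 3.85 (SE 0.29), while Nav2 and Zbed3 changed by -3.48 (SE 0.21) and -3.13 (SE 0.26). In all 1036 genes rose and 759 fell, or 14.5% (1863 and 1266, or 25.2%, without the doubted array), and 872 rose and 968 fell under quantile normalization. The percent was 8.96 without 4-cell replicate 2. Early activation had 5 of 17 up and 1 down (7 and 2 without the doubted array; adjusted p = 0.473).

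From the 4-cell to the 8-cell stage more trophectoderm genes rose in the mouse than in the steps before. The transcription factor Cdx2 rose by 5.36 (SE 0.25) from 4.83 ± 0.10 to 10.18 ± 0.60, Cldn4 by 4.66 (SE 0.19), Krt8 by 4.02 (SE 0.26) and Aqp3 by 3.92 (SE 0.26), with 15 of 39 genes up and 0 down (15 over the list alone, 18 and 1 without the doubted array; adjusted p = 0.197). The pluripotency factors Tfcp2l1 and Pou5f1 rose by 5.79 (SE 0.23) and 3.49 (SE 0.25), and Nanog changed by -2.25 (SE 0.39), with 6 of 26 up and 2 down. Early activation genes fell, Spz1 by -4.77 (SE 0.31), Klf17 by -3.51 (SE 0.28) and Tdpoz1 by -3.39 (SE 0.28), 9 of 17 in all with 0 up (1 and 11 over the list alone, 1 and 10 without the doubted array; adjusted p = 0.0453, and 0.119, no longer passing, without the doubted array). Of 19 oocyte genes 0 rose and 10 fell, also over the list alone and without the doubted array, Bcl2l10 by -4.32 (SE 0.20), Oosp1 by -3.70 (SE 0.30) and Btg4 by -3.42 (SE 0.35) (adjusted p = 0.0364, and 0.0638, no longer passing, without the doubted array). Oxidative phosphorylation had 28 of 70 up and 1 down (38 and 1 without the doubted array; adjusted p = 0.197). Ribosome biogenesis had 2 of 55 up and 14 down with a mean change of -0.43 (2 and 16 over the list alone, 4 and 24 without the doubted array; adjusted p = 0.4996). Outside the lists Dennd11 and Gdap1 fell most, with changes of -5.60 (SE 0.35) and -5.44 (SE 0.37). With these changes the 3 prime minus 5 prime difference of the actin control, a sign of RNA quality, rose from between 1.72 and 2.04 to between 3.58 and 4.10, and that of GAPDH from between 2.19 and 2.42 to between 2.72 and 2.90. In all 1138 genes rose and 1513 fell, or 21.4% (1774 and 2213, or 32.2%, without the doubted array).

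Between the mouse 8-cell stage and the morula the trophectoderm programme widened. Id2 rose by 5.27 (SE 0.35), Elf5 by 4.73 (SE 0.31), Gata2 by 4.30 (SE 0.49), Eomes by 4.25 (SE 0.23) and Tfap2a by 4.20 (SE 0.52), with 25 of 39 up and 1 down, also over the list alone (26 and 2 without the doubted array; adjusted p = 0.0638, and 0.00232, passing, without the doubted array). Sox17 and Lama1 of the primitive endoderm rose by 4.12 (SE 0.39) and 3.39 (SE 0.32), with 10 of 25 up and 1 down (12 and 1 without the doubted array; adjusted p = 0.0851). Cholesterol synthesis rose, Pmvk by 2.66 (SE 0.18) and Cyp51 by 2.53 (SE 0.67), with 10 of 19 up and 0 down (10 over the list alone, 11 and 1 without the doubted array; adjusted p = 0.234). Ribosome biogenesis fell further, Ddx21 by -2.59 (SE 0.29) and Fbl by -2.17 (SE 0.41), with 0 of 55 up and 30 down (36 over the list alone, 39 without the doubted array; adjusted p = 0.145). Adh1 and the lectin Lgals1 rose by 7.07 (SE 0.18) and 6.998 (SE 0.19), and the alkaline phosphatase Alppl2 and the stathmin Stmn3 changed by -6.06 (SE 0.31) and -5.50 (SE 0.23). Oxidative phosphorylation had 25 of 70 up and 2 down (41 and 2 without the doubted array), early activation 1 of 17 up and 5 down, Sp110 by -3.95 (SE 0.23) (1 and 8), and the oocyte list 0 of 19 up and 4 down (0 and 6). The actin control difference rose to between 5.52 and 5.81, but that of GAPDH fell to between 2.12 and 2.62. In all 1402 genes rose and 1214 fell, or 21.1% (2076 and 1885, or 32.0%, without the doubted array), but 1313 and 1362 under quantile normalization.

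From the mouse morula to the blastocyst cholesterol synthesis and protein and energy supply genes fell. Sqle changed by -2.66 (SE 0.54), Fdps by -2.47 (SE 0.30) and Lss by -2.34 (SE 0.56), and without the doubted array by -1.78 (SE 0.34), -2.18 (SE 0.28) and -1.39 (SE 0.32), with 0 of 19 cholesterol genes up and 14 down (1 and 17 over the list alone, 14 down without the doubted array; adjusted p = 0.378, and 0.0225, passing, without the doubted array). The median change of that list was -1.52, and -0.83 without the doubted array. Proteasome subunits had 0 of 34 up and 18 down (14 down without the doubted array; adjusted p = 0.378), oxidative phosphorylation 1 of 70 up and 21 down (2 and 22; adjusted p = 0.435) and ribosomal proteins 1 of 41 up and 15 down (0 and 13; adjusted p = 0.474). Of 35 mitosis genes 1 rose and 11 fell, Cdk1 by -2.98 (SE 0.43), and of 39 trophectoderm genes 2 rose and 7 fell. The oocyte list had a median change of 0.15 and a mean of -0.03, with opposite signs. The salivary protein gene Dcpp3 and the copper chaperone Atox1 rose by 3.31 (SE 0.48) and 2.97 (SE 0.49), and Gabarap and Dut changed by -3.25 (SE 0.31) and -3.19 (SE 0.44). In all 751 genes rose and 1427 fell, or 17.6% (939 and 1270, or 17.8%, without the doubted array). The percent was 0 with only the arrays of the compared stages, 36.5 without blastocyst replicate 1, 9.85 without morula replicate 1 and 8.42 without morula replicate 3.

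Over the whole mouse course Bcl2l10, Oosp1 and Btg4 of the oocyte list were among the 8 named falls, and Krt18, Cdx2 and Aqp3 of the trophectoderm list among the 8 named rises. Bcl2l10 fell from 13.18 ± 0.17 to 4.77 ± 0.23, a change of -8.42, SE 0.20, adjusted p = 3.64e-14, and Oosp1, Rgs2 and the homeobox gene Obox2 changed by -8.25 (SE 0.30), -8.14 (SE 0.51) and -8.09 (SE 0.25). Btg4, Tent5c, Mphosph6 and Dnajb4 changed by -7.51 (SE 0.35), -7.36 (SE 0.28), -7.35 (SE 0.47) and -7.26 (SE 0.48). The stress gene Ndrg1 rose by 7.52, SE 0.28, adjusted p = 2.25e-12, Krt18 by 7.22 (SE 0.35), Crxos by 7.14 (SE 0.20), the dipeptidase Cndp2 by 7.10 (SE 0.20), Cdx2 by 7.02 (SE 0.25), Pramel7 by 7.02 (SE 0.21), Aqp3 by 6.98 (SE 0.26) and Star by 6.89 (SE 0.27). Of 19 oocyte genes 0 rose and 18 fell, also over the list alone and without the doubted array (adjusted p = 0.00141). Of 41 ribosomal protein genes 40 rose and 0 fell (40 over the list alone, 40 and 1 without the doubted array; adjusted p = 0.0133). Oxidative phosphorylation had 56 of 70 up and 1 down, trophectoderm 28 of 39 up and 3 down, and primitive endoderm 13 of 25 up and 2 down (14 and 0 without the doubted array), with adjusted p = 0.0896 with an estimated correlation for all 3. Without the doubted array oxidative phosphorylation passed with adjusted p = 0.0193 and trophectoderm with 0.00637. Mitosis had 2 of 35 up and 24 down (3 and 22), stress 13 of 24 up and 4 down, Asns by 6.22 (SE 0.24), and glycolysis 7 of 18 up, Slc2a3 by 6.56 (SE 0.19), and 5 down, Ldhb by -5.81 (SE 0.27) (9 and 5). In all 3215 genes rose and 3215 fell, or 51.9% (3625 and 3327, or 56.1%, without the doubted array; 3161 and 3422 under quantile normalization), and 65.2% differed between any stages (71.8% without it).

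**Figure D3:**
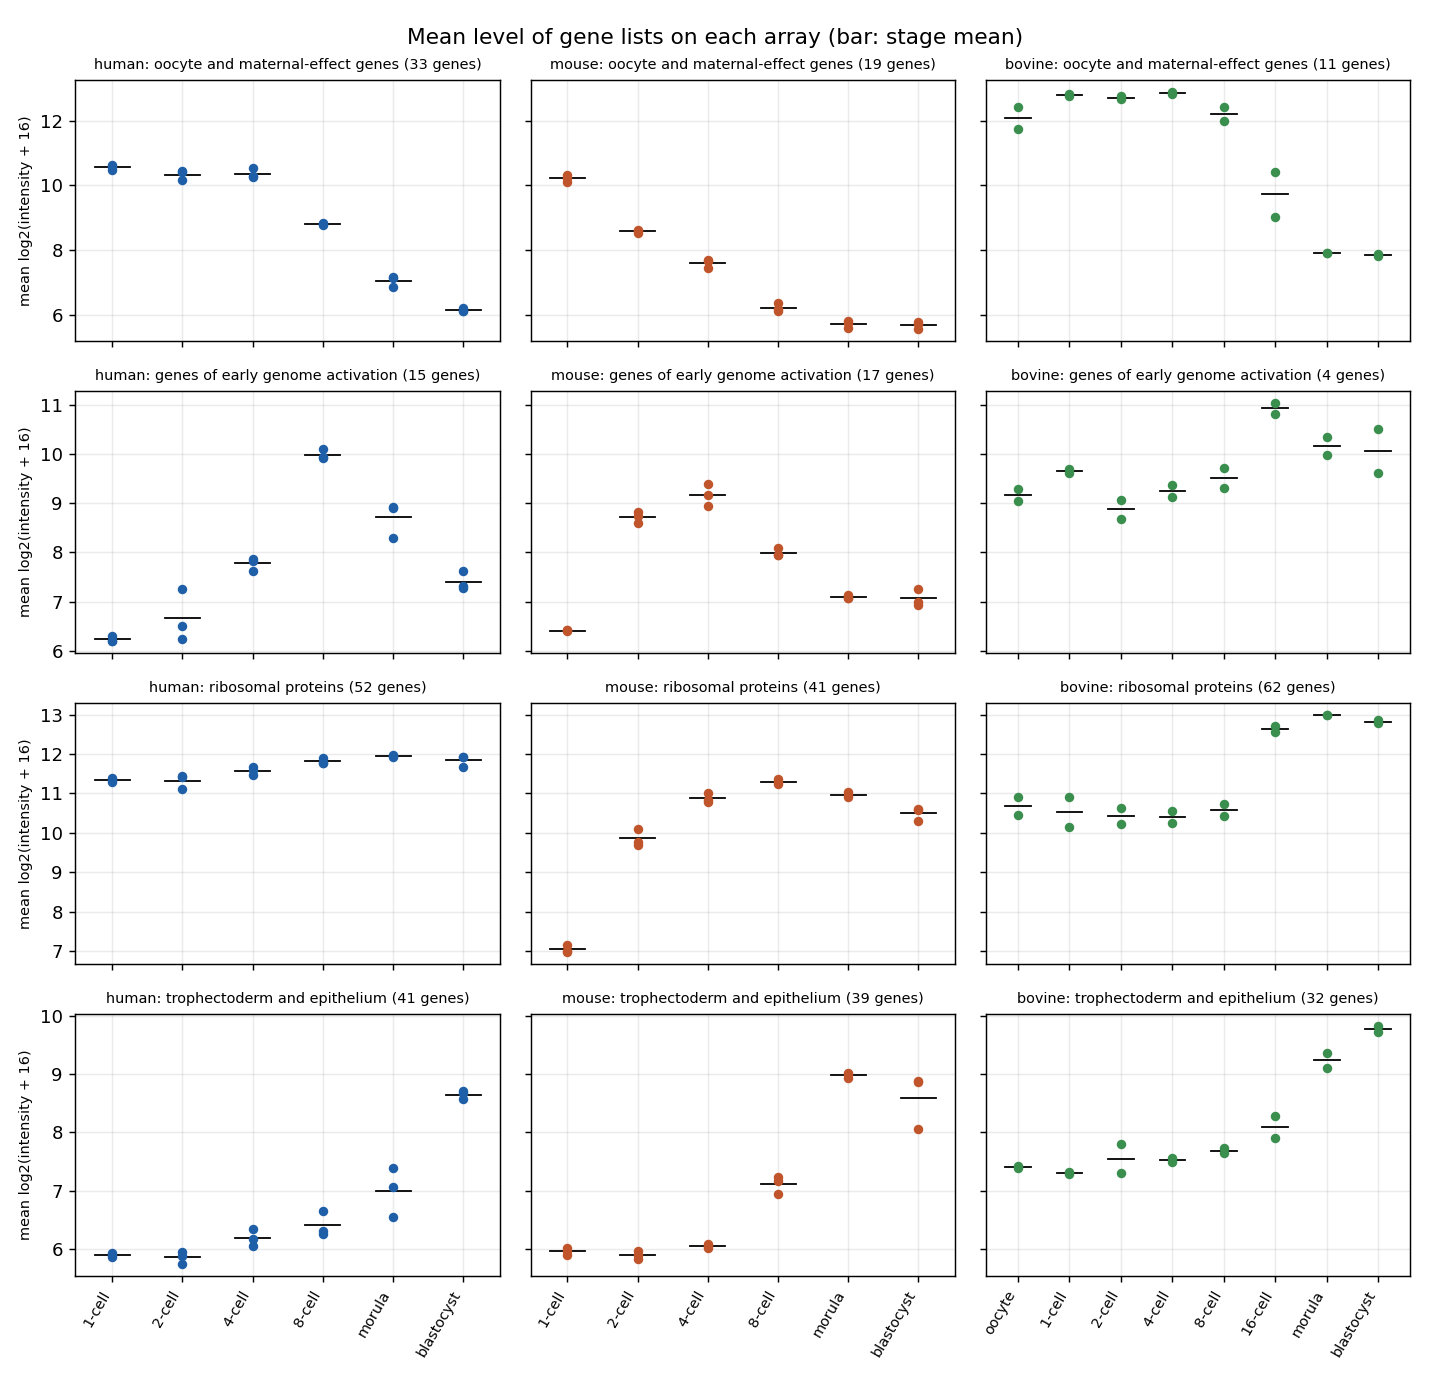
Mean log2(intensity + 16) of 4 gene lists in each array, by stage and species, with a bar at the stage mean. Oocyte genes fell from the 4-cell stage in human, from the 1-cell stage in mouse and from the 8-cell stage in bovine embryos, and the trophectoderm list rose late in each.

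In the bovine series, with 2 arrays per stage, few genes were called before the 8-cell stage, and with only the arrays of the compared stages none up to there or from the morula to the blastocyst. Between the oocyte and the 1-cell embryo ribosome assembly genes rose, RRP1 by 3.80 (SE 0.72), NOP14 by 2.87 (SE 0.46), PPAN by 2.73 (SE 0.33), NOP2 by 2.72 (SE 0.45), NHP2 by 2.52 (SE 0.50) and DKC1 by 1.68 (SE 0.29). Of the 44 in that list 6 rose and 0 fell (10 and 1 over the list alone, 5 and 0 without the doubted array), with adjusted p = 0.000965. The maternal-effect gene NLRP5 rose by 2.14 (SE 0.39). Cumulus markers moved with this step, the inhibin subunit INHA by -2.21 (SE 0.40), with a median change of -0.40 (adjusted p = 0.424, and 0.0369 with the preset correlation). VIM stood at 6.87 and 5.99 in the oocyte and 4.75 and 4.79 in the 1-cell arrays, and FST at 6.99 and 7.33 and at 5.57 and 5.36. ARMC7 and the glutaredoxin GLRX3 rose by 4.87 (SE 0.65) and 4.35 (SE 0.80), and the mRNA export factor THOC6 and the ribosome-bound RACK1 changed by -3.25 (SE 0.57) and -2.84 (SE 0.36). In all 104 genes rose and 13 fell, or 1.28% (125 and 20, or 1.58%, without the doubted array). The percent ran from 0.0983 to 0.623 as each array of these stages was left out in turn, where the lone array of the stage was assumed to vary like the other groups.

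From the bovine 1-cell to the 2-cell stage SRP68 of the signal recognition particle and ADNP2 rose by 3.29 (SE 0.55) and 3.22 (SE 0.63), and the RNA binder MEX3C and the cell death regulator BFAR changed by -6.61 (SE 0.73) and -6.51 (SE 1.05). In all 11 genes rose and 86 fell, or 1.06% (13 and 90, or 1.13%, without the doubted array). Quantile normalization gave 14 and 51 and lifted the median change of all genes by 0.15, and subtracting each array's median lifted it by 0.25. The percent ran from 0.251 to 2.34 as arrays were left out in turn. From the 2-cell to the 4-cell stage the translation factor EIF2B1 and the clock regulator CIPC rose by 5.06 (SE 0.91) and 4.91 (SE 0.78), and the transport factor XPO4 and the splicing factor SRSF11 changed by -5.99 (SE 0.93) and -4.66 (SE 0.66). Here 30 genes rose and 15 fell, or 0.492% (31 and 20, or 0.557%, without the doubted array), and 22 rose and 17 fell under quantile normalization. Here it ran from 0.240 to 2.76. No list passed in either step.

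Between the bovine 4-cell and 8-cell stages RSRP1, of a splicing factor family, rose from 4.20 ± 0.10 to 12.47 ± 0.07, a change of 8.27 (SE 0.51). The cell cycle inhibitor RPRM rose by 7.27 (SE 1.31), and the histone chaperone NASP and the respiratory assembly factor COA5 changed by -7.42 (SE 1.16) and -5.94 (SE 0.85). In all 119 genes rose and 81 fell, or 2.18% (119 and 85, or 2.23%, without the doubted array). The percent ran from 1.82 to 4.61 as arrays were left out. Oxidative phosphorylation had 0 of 72 genes up and 5 down (adjusted p = 0.454).

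The step from the 8-cell to the 16-cell stage had the most calls in bovine embryos with all arrays in the fit, and oocyte transcripts fell there. GDF9 fell from 11.07 ± 0.34 to 6.13 ± 0.03, a change of -4.94 (SE 0.53), and the importin KPNA7, BMP15 and NLRP5 changed by -4.35 (SE 0.66), -4.08 (SE 0.58) and -3.10 (SE 0.39). Ribosomal and mitochondrial genes rose, RPL22 by 5.63 (SE 1.18), RPS27 by 4.24 (SE 0.93), the respiratory chain subunits UQCR10 and COX4I1 by 6.24 (SE 0.92) and 5.72 (SE 1.07) and the ATP synthase subunit ATP5PD by 6.20 (SE 0.36). The pyruvate dehydrogenase subunit PDHA1 rose by 6.12 (SE 0.51), from 5.75 ± 0.15 to 11.87 ± 0.44, and the proteasome subunit PSMB6 by 6.53 (SE 1.54). TEAD4 and CDH1 of the trophectoderm list, KLF5 of the pluripotency list, and GATA6 and SPARC of the primitive endoderm list rose by 4.96 (SE 0.50), 4.51 (SE 0.49), 5.17 (SE 0.59), 4.74 (SE 0.62) and 4.38 (SE 0.39).

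Of 11 bovine oocyte genes 0 rose and 7 fell at the 8-cell to 16-cell step (1 and 10 over the list alone, 8 down without the doubted array; adjusted p = 0.0794, and 0.0417, passing, without the doubted array). Ribosomal proteins had 29 of 62 up and 1 down, RPL21 by -2.07 (SE 0.48) (41 and 1 over the list alone, 15 and 1 without the doubted array; adjusted p = 0.0794). Oxidative phosphorylation had 25 of 72 up and 0 down (28 over the list alone, 15 and 2 without the doubted array; adjusted p = 0.0765). Proteasome subunits had 10 of 29 up and 1 down (11 and 1 over the list alone, 5 and 1 without the doubted array; adjusted p = 0.145). Of the 4 measured early activation genes TMEM92 and EIF1AX rose by 3.25 (SE 0.47) and 2.14 (SE 0.61), and the list was too short to test. Of 9155 genes 951 rose and 562 fell, or 16.5%, against 2.56% with only the arrays of the compared stages. Without the doubted array 860 rose and 651 fell, again 16.5%. Quantile normalization gave 827 and 708, and subtracting each array's median lowered the median change of all genes by 0.11. Changes over 2-fold numbered 948 up and 559 down.

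The largest bovine rises at this step were in the mitochondrial thiolase ACAT1, 7.51 (SE 1.26), the magnesium transporter MAGT1, 7.48 (SE 0.67), the microtubule binder CLASP1, 7.24 (SE 1.61), CCDC86, 7.15 (SE 0.82), the tRNA modifier YRDC, 7.04 (SE 1.10), the tumour suppressor RASSF1, 7.04 (SE 0.59), CHGA, 6.90 (SE 0.77), and MDFIC, 6.89, SE 0.26, adjusted p = 8.58e-07. The largest falls were in the histone methyltransferase NSD3, -7.46 (SE 1.17), the clock gene PER2, -7.37, SE 0.46, adjusted p = 1.23e-05, and the mitochondrial fusion gene MFN2, -7.10 (SE 0.52). SIX3, RPRM, the glucose carrier SLC5A1, ZNF362 and RFX5 changed by -7.06 (SE 1.02), -7.04 (SE 1.31), -7.02 (SE 0.68), -6.94 (SE 0.84) and -6.94 (SE 0.56). Of 23 cumulus markers 0 rose and 2 fell, STAR by -4.38 (SE 0.75) and VCAN by -2.26 (SE 0.57). In the 16-cell arrays VIM stood at 11.32 and 4.70, LUM at 10.56 and 4.46, FST at 10.05 and 5.36 and COL1A2 at 11.37 and 5.66. The other lists had few calls, ribosome biogenesis 8 of 44 up and 2 down (6 and 2 without the doubted array), trophectoderm 5 of 32 up and 0 down (6 and 3), cholesterol synthesis 2 of 17 up and 1 down (0 and 3), and oviduct, blood and sperm markers 2 of 15 up.

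From the bovine 16-cell stage to the morula KRT18 rose from 4.90 ± 0.48 to 11.90 ± 0.57, a change of 6.998 (SE 0.44), and CLDN7 by 4.84 (SE 0.73). In the trophectoderm list 7 of 32 rose and 0 fell (11 and 1 over the list alone, 7 without the doubted array; adjusted p = 0.077). The fibronectin FN1 rose by 6.18 (SE 1.57) and ESYT2 by 6.92 (SE 0.69). MOS and ZP2 changed by -5.00 (SE 0.63) and -3.83 (SE 0.33), with 0 of 11 oocyte genes up and 5 down (1 and 7 over the list alone, 1 and 5 without the doubted array; adjusted p = 0.118). ZCCHC12 and FHL1 changed by -6.49 (SE 1.06) and -6.36 (SE 1.24), and oxidative phosphorylation had 7 of 72 up and 0 down (adjusted p = 0.077). In all 463 genes rose and 261 fell, or 7.91% (556 and 275, or 9.08%, without the doubted array). Subtracting each array's median gave 368 and 371 and lowered the median change by 0.26. The percent was 2.72 without morula replicate 1 and 3.19 without morula replicate 2.

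From the bovine morula to the blastocyst the steroid enzyme HSD3B1 and the ubiquitin-like UBD rose by 5.80 (SE 1.02) and 4.70 (SE 0.67), and ETNPPL and the phosphatase DUSP26 changed by -3.59 (SE 0.40) and -3.46 (SE 0.37). Ribosome biogenesis genes had a median change of -0.64 with no gene called, and adjusted p = 0.00456. Cholesterol synthesis had 1 of 17 up and 0 down with a median change of 1.58 (adjusted p = 0.0683), and trophectoderm 2 of 32 up (adjusted p = 0.0529). In all 42 genes rose and 13 fell, or 0.601% (47 and 18, or 0.710%, without the doubted array). The percent ran from 0.0437 to 0.644 as arrays were left out.

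Over the bovine course from the 1-cell stage to the blastocyst KRT18 rose from 4.52 ± 0.01 to 13.10 ± 0.35, a change of 8.57, SE 0.44, adjusted p = 1.38e-06, and GATA6 by 8.52 (SE 0.62). The amino acid transporter SLC38A2, the protease PLAU, MPZL2, WDR37, KRR1 and the GTPase RND3 rose by 8.32 (SE 0.52), 8.02 (SE 0.92), 7.82 (SE 1.32), 7.77 (SE 1.14), 7.74 (SE 1.61) and 7.72 (SE 0.68). The oocyte importin KPNA7 changed by -8.20, SE 0.66, adjusted p = 2.02e-05, and RGS16, TECTB, ALG13, GJC1, ARMC2, CASP1 and SRPX by -7.72 (SE 0.39), -7.53 (SE 0.40), -7.38 (SE 0.52), -7.23 (SE 0.59), -7.08 (SE 1.40), -7.04 (SE 0.63) and -6.98 (SE 0.57). Of 32 trophectoderm genes 17 rose and 0 fell, CLDN4 by 7.18 (SE 0.77) and CLDN6 by 6.57 (SE 0.40) (20 over the list alone, 19 and 1 without the doubted array; adjusted p = 0.0115). Of 11 oocyte genes 0 rose and 10 fell, ZP2 by -6.90 (SE 0.33) (10 over the list alone, 9 without the doubted array; adjusted p = 0.0356). Oxidative phosphorylation had 26 of 72 up and 0 down (32 over the list alone, 25 without the doubted array; adjusted p = 0.0356). Glycolysis had 6 of 19 up and 0 down, PDHA1 by 6.97 (SE 0.51) and ENO1 by 4.94 (SE 0.77) (7 over the list alone, 6 without the doubted array; adjusted p = 0.0436).

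Further bovine groups over the course were ribosomal proteins with 36 of 62 up and 1 down (44 and 1 over the list alone, 31 and 1 without the doubted array; adjusted p = 0.0513), primitive endoderm with 5 of 19 up and 0 down, PDGFRA by 7.35 (SE 0.61) and FN1 by 6.66 (SE 1.57) (adjusted p = 0.0778), and mitosis with 0 of 23 up and 3 down. The stress gene FOS rose by 6.85 (SE 1.26). In all 1199 genes rose and 813 fell, or 22.0% (1279 and 905, or 23.9%, without the doubted array), and 39.0% differed between any stages (39.2% without it). The percent for the course ran from 12.4 to 15.8 as arrays were left out, and subtracting each array's median gave 1017 that rose and 995 that fell and lowered the median change by 0.22. Over all species 312 tests of a list in a comparison were made. With the preset correlation 127 passed, 84 up and 43 down, and with an estimated correlation 21 passed, 10 up and 11 down. When arrays were regrouped at random, the preset correlation gave a median of 37 calls in human, against the real 54, and of 36 in mouse, against the real 46. Without the doubted arrays 23 passed with an estimated correlation, of which 16 had passed with all arrays, 5 calls being lost and 7 gained. The calls of NHP2, ADNP2, EIF2B1, PSMB6, EIF1AX and FHL1 in the bovine steps where they are named ended without the doubted array, with adjusted p from 0.0511 to 0.118.

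Genes with the same symbol were compared between species over the course from the 1-cell stage to the blastocyst. BCL2L10 and OOSP genes fell in human and mouse, KRT18 rose in all 3 species, and GATA6 rose in human by 5.48 (SE 0.32) and in bovine by 8.52. Across 10406 genes of human and mouse Pearson's r of the log2 changes was 0.270 (Spearman's rho 0.232), across 8303 genes of human and bovine 0.290 (rho 0.285), and across 6789 genes of mouse and bovine 0.240 (rho 0.226). Genes are not independent replicates, and an SE from leaving out single arrays was 0.0209, 0.0246 and 0.0320. Of genes called in both species, 66.1% of 3351 changed in the same direction in human and mouse, 74.6% of 1206 in human and bovine, and 71.5% of 951 in mouse and bovine.

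In human and mouse 1028 genes rose in both, where 715 were expected (odds ratio 2.13, 2-sided Fisher's exact p = 2.66e-54), and 1187 fell in both, where 788 were expected (odds ratio 2.47, Fisher's exact p = 1.47e-81). In human and bovine 484 rose in both with 299 expected (odds ratio 2.43, Fisher's exact p = 9.42e-39), and 416 fell with 216 expected (odds ratio 3.47, Fisher's exact p = 1.34e-57). In mouse and bovine 395 rose with 256 expected (odds ratio 2.22, Fisher's exact p = 2.27e-26), and 285 fell with 169 expected (odds ratio 2.501, Fisher's exact p = 1.09e-25). These tests treat genes as independent, which they are not. Of 6467 genes measured in all 3 species 207 rose in each, where 69.96 were expected, and 175 fell in each, where 46.8 were expected.

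The steps with most calls resembled each other across species. The human 4-cell to 8-cell step had r = 0.209 with the mouse 1-cell to 2-cell step and 0.178 with the bovine 8-cell to 16-cell step, and the mouse and bovine steps had 0.152 with each other. Their SE from leaving out single arrays was 0.0222, 0.0518 and 0.0183. Late steps resembled each other as much. The human morula to blastocyst step had r = 0.209 with the mouse 8-cell to morula step, 0.173 with the bovine 16-cell to morula step and 0.172 with the bovine morula to blastocyst step, and the mouse 8-cell to morula step had 0.203 with the bovine morula to blastocyst step. The human 1-cell to 2-cell step, where no gene was called, had 0.184 with the mouse morula to blastocyst step. Other values were lower or negative, down to -0.147 for human 2-cell to 4-cell with mouse morula to blastocyst and for mouse 1-cell to 2-cell with bovine morula to blastocyst. The human and mouse morula to blastocyst steps had -0.114.

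**Figure D4:**
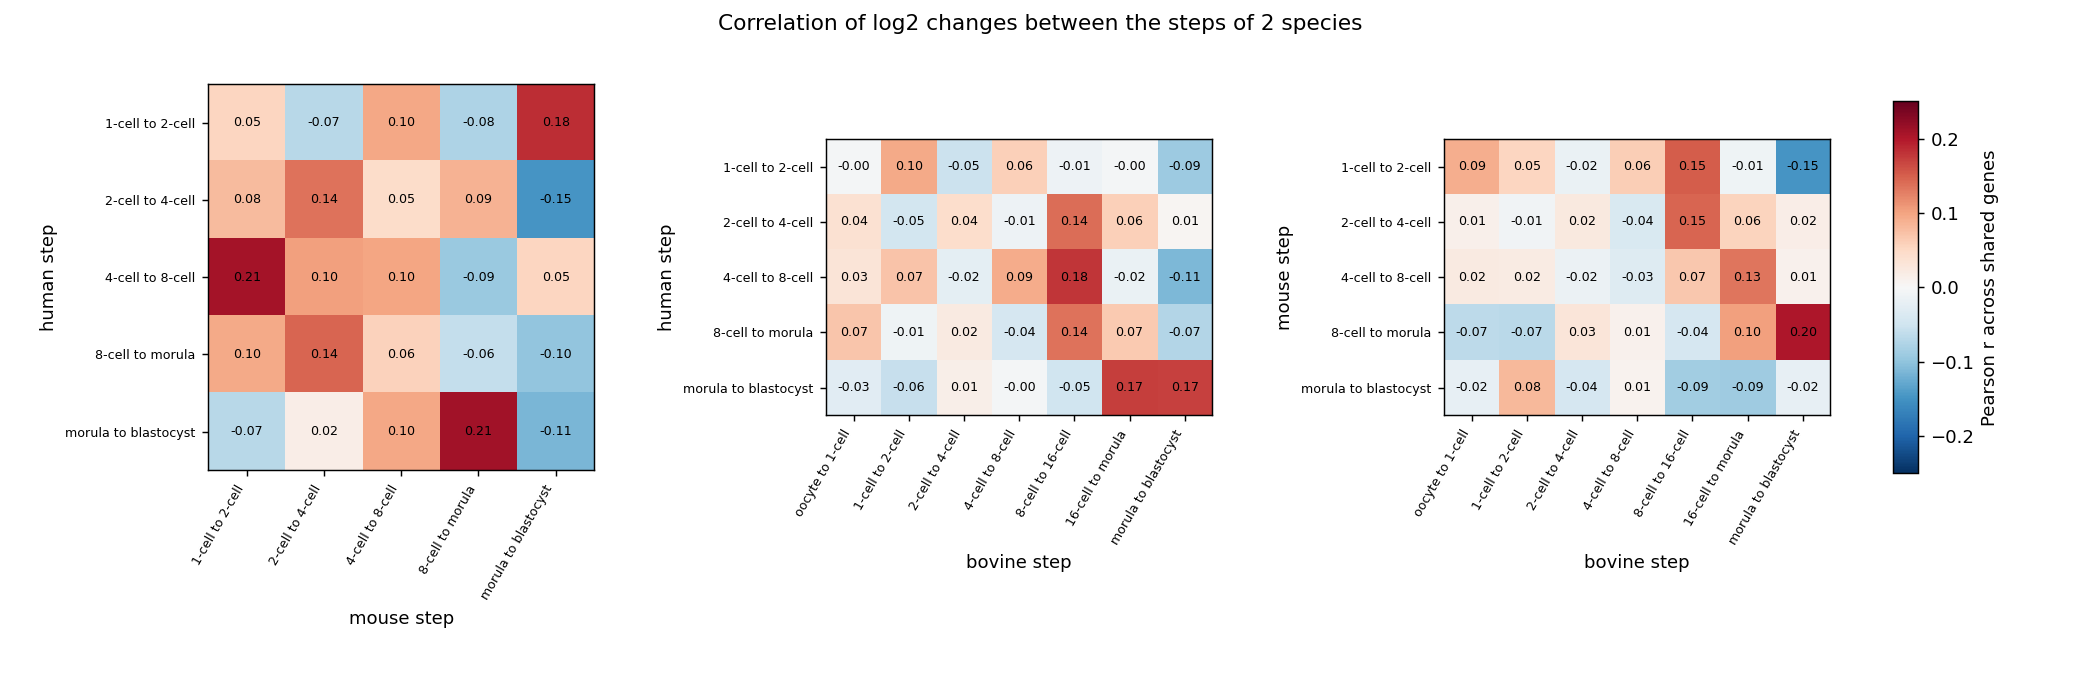
Pearson's r across genes between the log2 changes of each step in one species and each step in another, by color, for the 3 pairs of species. The human 4-cell to 8-cell step and the mouse 1-cell to 2-cell step had r = 0.209.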

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

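The tests of the 3 patterns weighed in this part and the next, on cumulus cell markers, on mouse blastocyst replicate 3 and on cholesterol synthesis, were chosen only after the results were seen.

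Cholesterol synthesis genes moved in opposite directions from the morula to the blastocyst in human and mouse. The mean log2 change was 1.59 in human, with 12 genes up and 0 down, and -1.39 in mouse, with 0 up and 14 down, a difference of 2.98. Mouse blastocyst replicate 3 alone is an unlikely source, since 14 genes also fell without that array, although the median of the list was then -0.83 in place of -1.52, and so is the scaling of the arrays, since under quantile normalization 11 genes fell in mouse and 11 rose in human. Different timing of the same change in the 2 species stays open as a hypothesis, in line with 10 genes that rose in mouse 1 step earlier, from the 8-cell stage to the morula. The difference itself was not tested.

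Other gene groups also moved in opposite directions in human and mouse, and these differences were not tested. Ribosome biogenesis changed from the 1-cell to the 2-cell stage by a mean of -0.27 in human with no gene called and by 1.90 in mouse with 39 up and 2 down, a difference of -2.17. At the 4-cell to 8-cell step the same list changed by 0.51 in human (20 up and 10 down) and by -0.43 in mouse (2 up and 14 down), a difference of 0.94, and at the 8-cell to morula step by 0.58 (18 up and 0 down) and by -0.97 (0 up and 30 down), a difference of 1.56. Early activation genes changed at the 4-cell to 8-cell step by 2.22 in human and by -1.18 in mouse, a difference of 3.40. Cholesterol synthesis changed at the 8-cell to morula step by -0.93 in human (0 up and 6 down) and by 1.05 in mouse (10 up and 0 down), a difference of -1.98. Without the doubted human arrays 4 of these genes fell and the median was -0.42 in place of -0.73. HMGCS1, FDPS and MSMO1 had the order of the cumulus marker STAR within the human 4-cell and 8-cell stages. Pluripotency genes changed at that step by 0.63 in human (12 up and 4 down) and by -0.32 in mouse (0 up and 5 down, or 3 and 10 without the doubted array), a difference of 0.95. Oxidative phosphorylation changed from the morula to the blastocyst by 0.61 in human (14 up and 0 down) and by -0.69 in mouse (1 up and 21 down), a difference of 1.30.

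Between mouse and bovine, at the 4-cell to 8-cell step, proteasome subunits changed by 0.55 (13 up and 2 down) and by -0.70 (0 up and 1 down), a difference of 1.25, and oxidative phosphorylation by 0.68 (28 up and 1 down) and by -0.75 (0 up and 5 down), a difference of 1.43. Cholesterol synthesis changed from the morula to the blastocyst by -1.39 in mouse and by 1.42 in bovine (1 up and 0 down), a difference of -2.81. No difference was tested.

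Single genes were called in opposite directions from the 1-cell stage to the blastocyst, by amounts that were not tested against each other. In human and mouse the sialyltransferase ST6GAL1 changed by 5.57 and -5.88 (difference 11.45), the lactate dehydrogenase subunit LDHB by 5.27 and -5.81 (difference 11.07) and the tubulin TUBB2A by 4.48 and -4.42 (difference 8.90). GRTP1 changed by -4.01 and 5.84 (difference -9.84) and the transcription factor BACH1 by -3.84 and 4.80 (difference -8.64). In human and bovine FN1 changed by -5.26 and 6.66 (difference -11.92), GGACT by -5.22 and 5.27 (difference -10.49), the chloride channel TTYH2 by -4.73 and 6.70 (difference -11.43), NHLRC3 by -4.73 and 5.09 (difference -9.82) and the transcription factor SOX4 by 4.92 and -4.54 (difference 9.46). In mouse and bovine RHPN2 changed by -5.97 and 5.72 (difference -11.69), PNRC1 by -4.80 and 5.31 (difference -10.12), STAR by 6.89 and -4.28 (difference 11.17), LDHB by -5.81 and 4.24 (difference -10.05) and the importin IPO8 by -3.97 and 6.54 (difference -10.51).

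Probe sets without a single gene name, which the comparisons above leave out, also carried signal. They were called between any stages in 31.4% of 13522 in human, 52.3% of 2246 in mouse and 25.9% of 10724 in bovine. Those with 1 name were called in 51.0%, 61.2% and 32.2%. From the 1-cell stage to the blastocyst 1999 unnamed probe sets rose and 1248 fell in human, 600 and 362 in mouse, and 996 and 600 in bovine.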

How the results depend on the processing

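The 2 or 3 arrays per stage limit every count, and the bovine counts before the 8-cell stage rested on single arrays. Percents of genes called that are not listed here stayed within 1.5-fold of the main value under every setting, and correlations within 1 SE, whereas the numbers that rose or fell and the counts within lists were not held to that limit. For the moved values below the cause was not tested.

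With only the arrays of the compared stages the percent called moved in bovine to 0 for oocyte to 1-cell, 1-cell to 2-cell, 2-cell to 4-cell, 4-cell to 8-cell and morula to blastocyst, to 2.56 for 8-cell to 16-cell and to 3.54 for 16-cell to morula. In human it moved to 0 for 2-cell to 4-cell and 10.8 for 8-cell to morula. In mouse it moved to 34.3 for 4-cell to 8-cell, 35.2 for 8-cell to morula, 0 for morula to blastocyst and 33.4 for 1-cell to blastocyst.

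With dim genes left out the bovine percents were 0.765 for 2-cell to 4-cell, 3.37 for 4-cell to 8-cell and 0.140 for morula to blastocyst. With all probe sets they were 0.562 for oocyte to 1-cell and 1.39 for 4-cell to 8-cell, and in human 0.0879 for 2-cell to 4-cell, 13.4 for 8-cell to morula and 11.04 for morula to blastocyst. With the mean of probe sets bovine 2-cell to 4-cell had 0.251. With a pseudocount of 1 human 2-cell to 4-cell had 0.106 and bovine morula to blastocyst 0.0437, which was 1.14 with a pseudocount of 64. For bovine 1-cell to 2-cell, median subtraction gave 0.579 and trend and robust variance 0.655. The replicate number as a block gave 0.382 for bovine morula to blastocyst. Residuals of arrays with the same number had r from -0.375 to 0.323 in human, from -0.221 to 0.239 in mouse and from -0.175 to 0.261 in bovine, and 1 of 18, 8 of 18 and 14 of 16 arrays were closest to their own number. No pairing was used, since only 10 of 45, 6 of 45 and 6 of 56 of these r were above 0.1, but a batch shared by bovine arrays of the same number was not excluded.

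Without the doubted arrays human 1-cell to 2-cell had 0.00506 and 2-cell to 4-cell 0.0101, and mouse 2-cell to 4-cell 25.2, 4-cell to 8-cell 32.2 and 8-cell to morula 32.0. Leaving out each array of the compared stages in turn gave from 0 to 0.00506 for human 1-cell to 2-cell and from 0 to 0.516 for 2-cell to 4-cell. In mouse it gave from 8.96 to 12.4 for 2-cell to 4-cell and from 8.42 to 36.5 for morula to blastocyst. In bovine it gave from 0.0983 to 0.623 for oocyte to 1-cell, from 0.251 to 2.34 for 1-cell to 2-cell, from 0.240 to 2.76 for 2-cell to 4-cell, from 1.82 to 4.61 for 4-cell to 8-cell, from 2.72 to 9.08 for 16-cell to morula, from 0.0437 to 0.644 for morula to blastocyst and from 12.4 to 15.8 for 1-cell to blastocyst.

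The gene list shift, 127 calls with the preset correlation, was 21 with an estimated one. Of the 127, 116 were kept under quantile normalization, 125 under median subtraction, 112 without dim genes and 117 with the mean of probe sets, and none was called in the opposite direction. The agreement between species over the course was 0.310 for human and mouse, 0.326 for human and bovine and 0.287 for mouse and bovine without dim genes, and 0.244 for human and mouse with a pseudocount of 1. The resemblance of the largest steps was 0.247 for human and mouse and 0.172 for mouse and bovine without dim genes. For human and mouse it was 0.237 under quantile normalization and 0.184 with a pseudocount of 1. For mouse and bovine it ran from 0.133 to 0.153 as arrays were left out in turn. Of the 148 named calls, 4 of 44 in human, 0 of 48 in mouse and 19 of 56 in bovine were lost in some fit without 1 array, and 138 were kept with the mean of probe sets, 141 with a pseudocount of 1, 143 with the block, 144 with a pseudocount of 64, 145 with trend and robust variance and 146 with each scaling and without dim genes. None was reversed.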

Other observations

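The tests on cumulus cell markers and on mouse blastocyst replicate 3 in this part were chosen only after the results were seen, whereas the regroupings of the arrays had been set beforehand.

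Cumulus and granulosa cell markers were high in single arrays of cleavage-stage embryos, where the median difference of the list from the other arrays of the stage was 1.09 in human 8-cell replicate 3, 0.44 in 4-cell replicate 2 and 0.71 in bovine 16-cell replicate 1, each at percentile 100 of 10000 random lists. As the arrays were picked for these markers, the percentile decides nothing, and RNA of cumulus or granulosa cells in these arrays is a candidate explanation that stays open, with no step named in the labels that removed such cells from human embryos. Of 26 markers 14 were over 1 higher and 0 over 1 lower in human 8-cell replicate 3. STAR, HSD3B2 and FST stood there at 10.49, 10.77 and 10.54. FSHR, COL1A2 and AMHR2 differed little within the stage. The scaling of the arrays is an unlikely source, since 10 of 10 falls remained under quantile normalization. Transcription by the embryo at the 8-cell stage could not be excluded. In all 8-cell arrays 4 of the 10 genes were above every 2-cell array, but RNA of other cells would give this too.

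Mouse blastocyst replicate 3 stood apart from the other blastocyst arrays, with r of 0.734 and 0.750 to them against 0.945 between those. A mean r of 0.710 with the morula and 0.742 with its own stage leaves an array of another stage open. The 3 prime minus 5 prime difference of actin was 7.18, against at most 5.81 in other mouse arrays. Genes above a level of 8 numbered 1756, against at least 2263. Both go with a low amount or quality of RNA. The GAPDH difference was 2.98, below the highest other 3.24, so RNA quality stays open. A more advanced embryo could not be told apart, with a mean r of 0.147 between its difference and the earlier changes. It differed over 8-fold in 128 genes above and 182 genes below the other arrays.

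For any difference between stages only the real one of 100 groupings of the arrays reached its percent. This was 60.1 in human against a highest other value of 14.3, and 65.2 in mouse against 6.27. Chance is thus an unlikely source of either. List calls with the preset correlation numbered 54 in human, reached by 2 of 100 groupings with a highest other value of 54, and 46 in mouse, reached by 5 of 100 with a highest other value of 47, so that by the limit of 5 in 100 chance is an unlikely source in human, although 1 other grouping gave as many, and stays open in mouse. The median of the other groupings was 37 in human and 36 in mouse, so that many calls of that kind also came without the real stage labels. As these groupings mix arrays of different stages, they cannot say how many calls arise without a difference between stages. With an estimated correlation list calls numbered 6 in human against a highest other value of 2, and 9 in mouse against 1. Chance is an unlikely source of these totals, but single lists were not tested by regrouping.

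Within pairs of stages the 6 arrays allow 10 splits into 3 against 3, too few for a share under 0.05. In human the real percent for 1-cell to 2-cell was 0 in 10 of 10 splits, and in each other comparison 1 of 10 splits reached the real percent. The highest other percent in human was 0 for 2-cell to 4-cell (real 0.187), 0.187 for 4-cell to 8-cell (real 37.2), 0.00506 for 8-cell to morula (real 21.4), 0 for morula to blastocyst (real 16.9) and 0 for 1-cell to blastocyst (real 47.0). In mouse it was 0 for 1-cell to 2-cell (real 32.6), 0.00807 for 2-cell to 4-cell (real 14.5), 0 for 4-cell to 8-cell (real 21.4), 0 for 8-cell to morula (real 21.1), 0.121 for morula to blastocyst (real 17.6) and 0 for 1-cell to blastocyst (real 51.9).

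Replicates of bovine cleavage stages differed more than those of other stages. The 2 arrays were over 8-fold apart in 724 genes at the 2-cell stage (r 0.843), 571 at the 4-cell stage (r 0.871), 678 at the 8-cell stage (r 0.857) and 634 at the 16-cell stage (r 0.859), against 39 in the oocyte, 112 at the 1-cell stage, 2 in the morula and 32 in the blastocyst. No human pair of arrays exceeded 61 genes, and no mouse pair outside the blastocyst exceeded 3.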
